A study of Homo sapiens with 6 samples.

How the data were processed

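T-HESC cells transfected with non-targeting siRNA (siNT, 3 libraries) or with siRNA against VDR (siVDR, 3 libraries) were assayed by ATAC-seq. Per the labels' protocols, lysed cells were tagmented with Tn5, and the DNA was amplified by PCR and purified on beads. Per the submitters' processing notes, adapters were removed with Trim Galore and the build was hg38. Per the series' design text, duplicate, unmapped and mitochondrial reads were removed, reads were trimmed to 9 bp, libraries were sampled at random to one depth, and siNT was compared with siVDR. The aligner, the peak caller, its threshold, and whether reads or intervals of the 3 libraries were merged are not given in the sources used here. Whether the 3 libraries came from separate cultures is not given either.

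The deposited values are positions of intervals in bp, in a 3-column list per group, with no level or score for an interval. Each list was taken as pooled over the 3 libraries of its group. Its name gives the group and the word merged, and names no library. The shortest intervals were 9 bp, the length of the trimmed reads, and the smallest gap between neighbours was 101 bp in both lists. A wide interval can therefore join several cut sites, and width was the only ranking the lists allow. The read depth of the libraries is unknown here, so no limit of detection can be given.

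Chromosomes 1 to 22 and X were used, and 111 siNT and 102 siVDR intervals on other sequences were left out. Intervals of the lists were compared by overlap of at least 1 bp. The counts were checked against bedtools 2.31.1. Intervals were placed at random within their chromosomes 100 times. Shares are given with exact (Clopper-Pearson) 95% intervals, and the ratio of interval numbers with the interval of the matching binomial share. Both cover counting error only. The 2 lists give no replicated values, so no test of the conditions and no p-value was computed, and leaving out a library was not possible.

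Gene positions came from an annotation table of GRCh38.p14, the assembly of which hg38 is the browser name, with 19974 protein-coding genes. The table gives each gene's start and end with no strand and no exons. The planned promoter was therefore replaced by a gene end, meaning within 1 kb of either annotated end of a protein-coding gene. Exons and introns were joined as gene body. Each interval was assigned to the nearest gene end within 50 kb, by its midpoint. A gene's state at its ends was both lists, siVDR only, siNT only or neither. In the state of both lists, the intervals of the lists need not overlap. These replacements were made when the table was seen. The planned search for motifs needs a genome sequence and was not run.

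The 19 gene lists, the comparisons, the named-gene rule and most alternatives were fixed before the data were examined. The lists cover decidualization, vitamin D metabolism and receptor, vitamin D receptor targets, repressive chromatin regulators, HOX genes, extracellular matrix, cell cycle, interferon response, inflammatory cytokines and NF-kB, Wnt signalling, TGF-beta and BMP signalling, AP-1 and immediate early genes, stromal identity, epithelial, leukocyte, endothelial and smooth muscle markers, housekeeping genes and olfactory receptors. Of the listed genes, 11 are in more than 1 list. For each list, the net gain (siVDR-only minus siNT-only) was set as a percentile among 10000 random lists of the same size, with ties counted by their middle. Random genes were matched on deciles of the number of intervals nearest to the gene in either list, which left 7 classes after ties. This number includes the intervals whose net is then compared, so a list with many siVDR-only sites is set against random genes that also have many, and a position within the central 95% does not show that the list has no excess. Matching on intervals in both lists alone, in 5 classes, was added after seeing the data. Percentiles of 2.5 to 97.5 are the central 95%. A percentile describes these 2 lists and is not a p-value. Random genes were drawn without regard to position, so random lists do not copy neighbouring genes that can share intervals, such as HOX genes.

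The named genes are VDR, and up to 4 members per direction from each list with a gene end in 1 list only, ordered by net gain of nearest sites. Added to these are the 10 genes with the largest net gain and the 10 with the largest net loss of nearest sites, and the 5 widest intervals of each list alone. PRL, IGFBP1, FOXO1, HOXA10, PGR and CYP24A1 were named whatever their state. The rule gives 84 genes, of which a part is printed.

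The alternatives were a minimum width of 200 bp, merging of intervals within 150 bp, autosomes only, reciprocal overlap of 50%, midpoints within 250 bp, a siVDR list reduced by width to the number of siNT intervals, the widest 50% of each list, windows of 500 bp and 2.5 kb, all annotated genes, nearest ends within 10 and 200 kb, and unmatched random lists. A minimum width of 50 bp in both lists, assignment to gene spans, leaving out each member of a list and a comparison within width classes were added after seeing the data. A comparison of symbol families, with 2000 random lists each, was not planned either.

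The scripts were tested on simulated data with the 19974 genes. All 200 planted and 100 removed intervals were found, a list with planted intervals reached the 100th percentile, and 4.50% of 200 unchanged lists lay beyond the central 95%. The values for the unchanged lists were drawn independently per gene, with a mean set by the matching number. That share therefore checks the code only, and not real lists with neighbouring genes. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.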

Results

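Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in T-HESC cells, an immortalized line of human endometrial stromal cells. The cells had been transfected with pooled non-targeting siRNA (siNT) or with siRNA against the vitamin D receptor gene VDR (siVDR), with 3 libraries in each group. The comparison asked which sites were accessible with and without knockdown of the receptor, a ligand-activated transcription factor that binds DNA with retinoid X receptors. The measurements were 2 lists of accessible intervals on hg38, 1 list per group, taken as pooled over its libraries. The lists carry no level, score or read depth, and the spread between libraries is unknown. No test of the conditions was therefore possible, and every difference describes these 2 lists only. The intervals in parentheses are exact 95% binomial intervals and cover counting error only.

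Knockdown cells had the longer list. The siVDR list held 73238 intervals over 6.65 Mb and the siNT list 45230 intervals over 3.26 Mb. The number of intervals was 1.62 times higher in siVDR (1.60 to 1.64) and the covered length 2.04 times higher. The excess was larger among wide intervals, with 10787 intervals of 200 bp or more in siVDR and 4738 in siNT, a ratio of 2.28. All 23 chromosomes examined had more intervals in siVDR. The ratio ran from 1.497 on chromosome 19 (1.41 to 1.60) to 1.77 on chromosome X (1.64 to 1.92). Many intervals were short, and 36.7% of the siNT list and 29.9% of the siVDR list were 9 bp wide. The median width was 19 bp in siNT (interquartile range 9 to 109) and 41 bp in siVDR (9 to 139).

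A larger share of siNT sites was also in the siVDR list than the reverse. The numbers of overlapping intervals were close, so this largely restates the longer siVDR list. Of the siNT intervals, 36024 overlapped a siVDR interval by at least 1 bp, or 79.7% (79.3 to 80.0), and 9206 were in siNT only. Of the siVDR intervals, 33895 overlapped a siNT interval, or 46.3% (45.9 to 46.6), and 39343 were in siVDR only. Placing the intervals at random on their chromosomes gave overlaps of 0.409% and 0.248%. The size of both shares depended on the setting. The siNT share was 38.1% with reciprocal overlap of 50%. The siVDR share was 65.5% with the siVDR list reduced by width to the number of siNT intervals. Lists so reduced are called lists of equal length below, which means equal in number of intervals and not in covered length. The sites in siNT only were short, with 76.8% at 9 bp and 3 of 200 bp or more. The sites in siVDR only had a median width of 11 bp, and 572 were 200 bp or wider. Where 1 siNT interval overlapped 1 siVDR interval, which gave 31364 pairs, the median width was 55 bp in siNT and 126 bp in siVDR. The siVDR interval was the wider in 77.5% of pairs and the siNT interval in 14.1%.

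**Figure D1:**
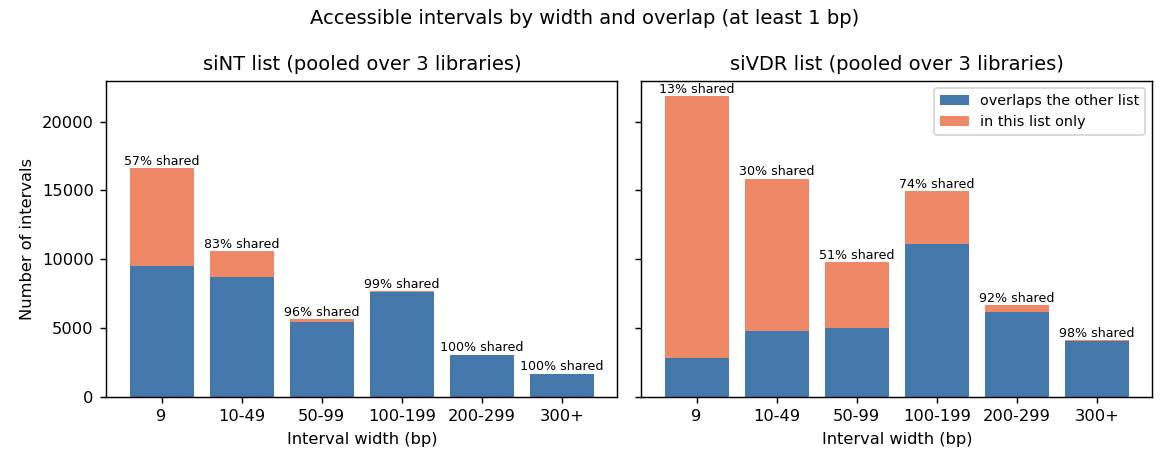
Number of accessible intervals (vertical axis) by interval width in bp (horizontal axis) in the siNT and siVDR lists, each taken as pooled over 3 libraries. Blue parts overlap the other list by at least 1 bp and orange parts do not. The share in both lists climbs with width, from 57.4% of 9-bp intervals to 100% of those of 300 bp or more in siNT, and from 12.9% to 98.3% in siVDR.

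Sites in both lists lay more often near protein-coding gene ends than sites in either list alone. Within 1 kb of an annotated end of a protein-coding gene lay 34.4% of the siVDR intervals in both lists (33.9 to 34.9). The share was 21.9% (21.5 to 22.3) for siVDR-only and 19.2% (18.4 to 19.98) for siNT-only intervals, against 2.55% after random placement. Shared sites were wider, and the difference varied with width. Among 9-bp siVDR intervals the shares were 23.3% (21.8 to 24.9) in both lists and 21.1% (20.6 to 21.7) in siVDR only, and among those of 300 bp or more they were 45.2% (43.7 to 46.8) and 5.80% (1.60 to 14.2). Gene bodies farther than 1 kb from a gene end held 41.8% of siVDR-only and 41.0% of siNT-only intervals, and 33.8% of those in both lists. The median distance to the nearest gene end was 9.99 kb for sites in both lists, 18.0 kb for siVDR-only and 20.4 kb for siNT-only sites. The gene table used gives no strand, so a gene end is either the start or the end of transcription.

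At the level of genes, 9465 of 19974 protein-coding genes (47.4%) had an interval near a gene end in both lists, though not always the same site. A further 1825 genes (9.14%) had one in siVDR only and 188 (0.941%) in siNT only, and 8496 had none. Among the siVDR-only genes, 22.96% shared the interval with the window of another gene. In 14 siVDR-only and 3 siNT-only genes, the interval overlapped the other list outside the window. With the siVDR list reduced to its widest intervals, as many as the siNT list holds, the counts were 1026 and 597 genes.

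VDR itself (chromosome 12, 47841537 to 47904994) was among the genes with a gene end in siVDR only. A 59-bp interval at 47904977 to 47905035 and a 9-bp interval at 47904786 to 47904794 lay at its higher-coordinate end. A 122-bp siVDR-only interval lay at 47867732 to 47867853 inside the gene. A site at 47881809 to 47882150 was 342 bp wide in siVDR and was listed in siNT as pieces of 91 and 22 bp. An siRNA acts on the mRNA, so these intervals do not measure the knockdown. Of the 9 genes of vitamin D metabolism and its receptors, CYP27A1, a vitamin D 25-hydroxylase, was the other with a gene end in siVDR only, through a 9-bp interval. CYP24A1, the vitamin D 24-hydroxylase induced by the receptor, had no interval near a gene end in either list, and its 2 nearest sites were in both lists. The 9 genes lay at the 88.5th percentile of matched random lists for gene ends and at the 10.9th for nearest sites, both within the central 95%.

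Among 20 known targets of the vitamin D receptor, 5 had a gene end in siVDR only and none in siNT only. They included IGFBP3, which encodes a binding protein of insulin-like growth factors, CD14, the lipopolysaccharide co-receptor, FBP1 and G0S2. Each of these had only 9-bp intervals at the gene end. The other gene, LRP5, had a 102-bp interval there. The net gain, siVDR-only minus siNT-only genes per 100 genes, was 25, at the 99.01st percentile of 10000 random gene lists matched on the number of nearby intervals. That number includes the siVDR-only and siNT-only intervals, so the matching takes up part of what is compared. Positions that cross the limits of the central 95% when random lists are matched on intervals in both lists alone, an alternative chosen after seeing the data, are therefore given as well. For gene ends this position was lost among intervals of 50 bp or more, a limit chosen after seeing the data, at the 46.6th percentile, with lists of equal length, at the 69.4th, and without CD14, at the 96.9th. For sites nearest to its genes within 50 kb, the list had 28 siVDR-only and 3 siNT-only intervals, at the 96.7th percentile, just inside the central 95%. That position was 97.3 among intervals of 50 bp or more, 98.0 with lists of equal length, 84.5 when matched on intervals in both lists, 82 by gene spans and 72.2 with unmatched random lists.

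The 26 genes of decidualization, the differentiation of stromal cells that prepares the endometrium for implantation, had 5 gene ends in siVDR only and none in siNT only. BMP2, a bone morphogenetic protein, and CEBPB, a transcription factor, each had 3 siVDR-only intervals among the sites nearest to the gene within 50 kb, and no siNT-only interval. Those of CEBPB were 9, 38 and 9 bp wide. Among intervals of 50 bp or more, CEBPB had 1 siNT-only and no siVDR-only site, and BMP2 had 1 siVDR-only and no siNT-only site. PGR, the progesterone receptor gene, had a gene end in siVDR only through a 9-bp interval at chromosome 11, 101129804 to 101129812. PRL, which encodes the decidual marker prolactin, had 2 siVDR-only sites nearby but none at a gene end, and IGFBP1, another decidual marker, had no interval in either list. FOXO1 and HOXA10, transcription factors of decidual cells, had gene ends in both lists. At HOXA10 the intervals did not overlap: the siNT interval was 10 bp wide and the siVDR interval 72 bp. The list lay at the 92.8th percentile for gene ends and at the 60.5th for the net gain of sites nearest to its genes, both within the central 95%, and at 98.9 and 99.5 among intervals of 50 bp or more.

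With intervals of all widths and the planned matching, genes of TGF-beta and BMP signalling had the highest percentile among the fixed lists for nearest sites. The 34 genes had 125 siVDR-only and 20 siNT-only sites, a net gain of 3.09 per gene against a mean of 2.24 in matched random lists (central 95%, 1.65 to 2.82), at the 99.7th percentile. Of the 34 genes, 29 had a net gain and none a net loss. No decidualization, cell cycle, interferon response, stromal or housekeeping gene had a net loss either, while 3 of 32 Wnt signalling genes did. The lack of losses is therefore not particular to this list. TGFB2, a TGF-beta ligand, had 11 siVDR-only and 2 siNT-only sites, and its lower-coordinate end held a 115-bp siVDR-only interval at chromosome 1, 218345799 to 218345913. BMPR1B, a BMP receptor, and SMAD1, a BMP signal transducer, each had 5 siVDR-only sites and no siNT-only site. With lists of equal length, the percentile was 93.9, and vitamin D receptor targets lay higher, at 98.0. Among intervals of 50 bp or more, the TGF-beta and BMP genes were at 98.8, below decidualization (99.5) and HOX genes (99.4). At that width, 25 of the TGF-beta and BMP genes had a net gain and 2, TGFB3 and GREM1, a net loss. Both of these had a gene end in siNT only, against 11 genes in siVDR only. At gene ends and with all widths, the TGF-beta and BMP list had 7 genes in siVDR only and none in siNT only. That placed it at the 95.85th percentile, inside the central 95%, but at 98.4 against unmatched random lists and 99.4 when matched on intervals in both lists. It stayed inside at 92.2 among intervals of 50 bp or more, 94.7 with lists of equal length and 96.6 with windows of 2.5 kb.

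The 31 extracellular matrix genes had 8 gene ends in siVDR only and 2 in siNT only. COL4A2 and COL4A1, the basement membrane collagens that lie head to head on chromosome 13, had 10 and 9 siVDR-only sites. Their gene ends held the same 2 intervals, of 18 and 9 bp, which are counted for each gene. Neither had a gene end in a list among intervals of 50 bp or more. COL6A3 had 6 siVDR-only sites and the matrix protease gene MMP2 had 5, both with no siNT-only site. TIMP2, an inhibitor of such proteases, and the laminin gene LAMA4 had a gene end in siNT only, through 9-bp intervals. LAMA4 nevertheless had 7 siVDR-only and 3 siNT-only sites nearby. The list lay at the 89.8th percentile for gene ends and at the 76.6th for nearest sites, both within the central 95%. When matched on intervals in both lists it lay beyond, at 98.8 for gene ends and 99.9 for nearest sites. For nearest sites it was also 98.6 among intervals of 50 bp or more and 100 against unmatched random lists. Among 24 stromal and mesenchymal genes, ENG and MME had a gene end in siVDR only and PDGFRA in siNT only. PDGFRA, the platelet-derived growth factor receptor alpha gene, had 10 siVDR-only and 1 siNT-only site nearby. Its siNT interval at the gene end, 109 bp at chromosome 4, 54228198 to 54228306, overlapped a siVDR interval that ended outside the 1-kb window. This list lay at the 15.7th and 76.3rd percentiles, and the latter was 99.97 when matched on intervals in both lists and 100 against unmatched random lists.

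Inflammatory cytokine and NF-kB genes had 52 siVDR-only and 6 siNT-only sites over 25 genes, a net gain of 1.84 per gene, at the 99.2nd percentile. For gene ends, with 4 genes in siVDR only, the list lay at the 86.3rd percentile, inside the central 95%. CXCL8, the neutrophil chemokine gene, had 4 siVDR-only sites, including a 211-bp interval at its lower-coordinate end (chromosome 4, 73740513 to 73740723). CCL7, IL1B and TLR2 also had a gene end in siVDR only. The position for nearest sites was not stable: it was 72.1 among intervals of 50 bp or more, 75.8 with lists of equal length, 85.1 for sites within 10 kb and 94.6 without NFKBIA. AP-1 and immediate early genes lay at the 39.9th percentile for gene ends and at the 94.6th for nearest sites, which was 99.3 when matched on intervals in both lists and 100 against unmatched random lists. FOSB, IER2 and ZFP36 had a gene end in siVDR only and NR4A1 in siNT only. Interferon response genes lay at the 38.7th and 75.3rd percentiles, with IFIT2 and OAS1 in siVDR only.

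With intervals of all widths, the remaining regulatory lists lay within the central 95% of matched random lists on both measures. Of 36 cell cycle genes, 30 had a gene end in both lists, and CCND1, encoding cyclin D1, and the inhibitor gene CDKN1C had one in siVDR only (24.5th percentile for gene ends, 48.0th for nearest sites). Of 32 Wnt signalling genes, TCF7L2, AXIN1, LEF1 and LRP5 had a gene end in siVDR only (63.8th and 21.5th). Of 23 repressive chromatin regulators, HDAC5, CBX7 and DNMT3A did (67.9th and 29.8th). HDAC5, a histone deacetylase gene, had 8 siVDR-only and 1 siNT-only site. Of 39 HOX genes, the patterning factors, 5 had a gene end in siVDR only, among them HOXA5, HOXA6, HOXA9 and HOXA13 (88.0th and 81.5th, and 99.3rd and 99.4th among intervals of 50 bp or more). The HOXA9 interval was 250 bp wide, at chromosome 7, 27165547 to 27165796. Neighbouring HOX genes can share an interval, which the random lists do not copy.

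No interval lay at the gene ends of 13 of 20 endometrial epithelial, 17 of 22 leukocyte, 15 of 16 endothelial and 7 of 14 smooth muscle and pericyte markers, and of 379 of 390 olfactory receptor genes, a set taken as closed in this cell type. Over all protein-coding genes the share was 42.5%. Epithelial markers had a net gain of 0.5 per gene, at the 2.54th percentile of matched random lists, which was just inside the central 95%. The percentile was 0.4 for sites within 10 kb, 1.45 within 200 kb and 0.56 by gene spans, but 35.7 with lists of equal length and 42.9 among intervals of 50 bp or more. GRHL2, an epithelial transcription factor, had 5 siNT-only and 2 siVDR-only sites, which covered 55 and 18 bp in all. Its siNT-only intervals at chromosome 8, 101671384 to 101671394 and 101678281 to 101678290, lay within 1 kb of sites in both lists. For gene ends, the epithelial list lay at the 64.4th percentile, leukocyte markers at the 68.4th and endothelial markers at the 12.4th. For nearest sites, leukocyte markers lay at the 34.3rd and endothelial markers at the 81.8th. Smooth muscle and pericyte markers lay at the 1.74th percentile for gene ends, through MYH11 in siNT only and no gene in siVDR only, and at the 76.3rd for nearest sites, or 98.3 when matched on intervals in both lists and 98.2 against unmatched random lists. Without MYH11 the former was 16.0, and among intervals of 50 bp or more it was 63.9. Olfactory receptors lay at the 0.890th and 76.5th percentiles, with 5 genes in siVDR only, at the 14.4th for gene ends with lists of equal length, and at 0 for nearest sites both against unmatched random lists and when matched on intervals in both lists. Of 27 housekeeping genes, 24 had a gene end in both lists and 3 in siVDR only, YWHAZ, HPRT1 and CHMP2A (57.3rd and 93.1st). Over the 19 lists, 3 positions for gene ends and 2 for nearest sites lay beyond the central 95%. By chance, 0.95 of each were to be expected if genes varied independently. When matched on intervals in both lists, 5 and 7 lay beyond it.

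**Figure D2:**
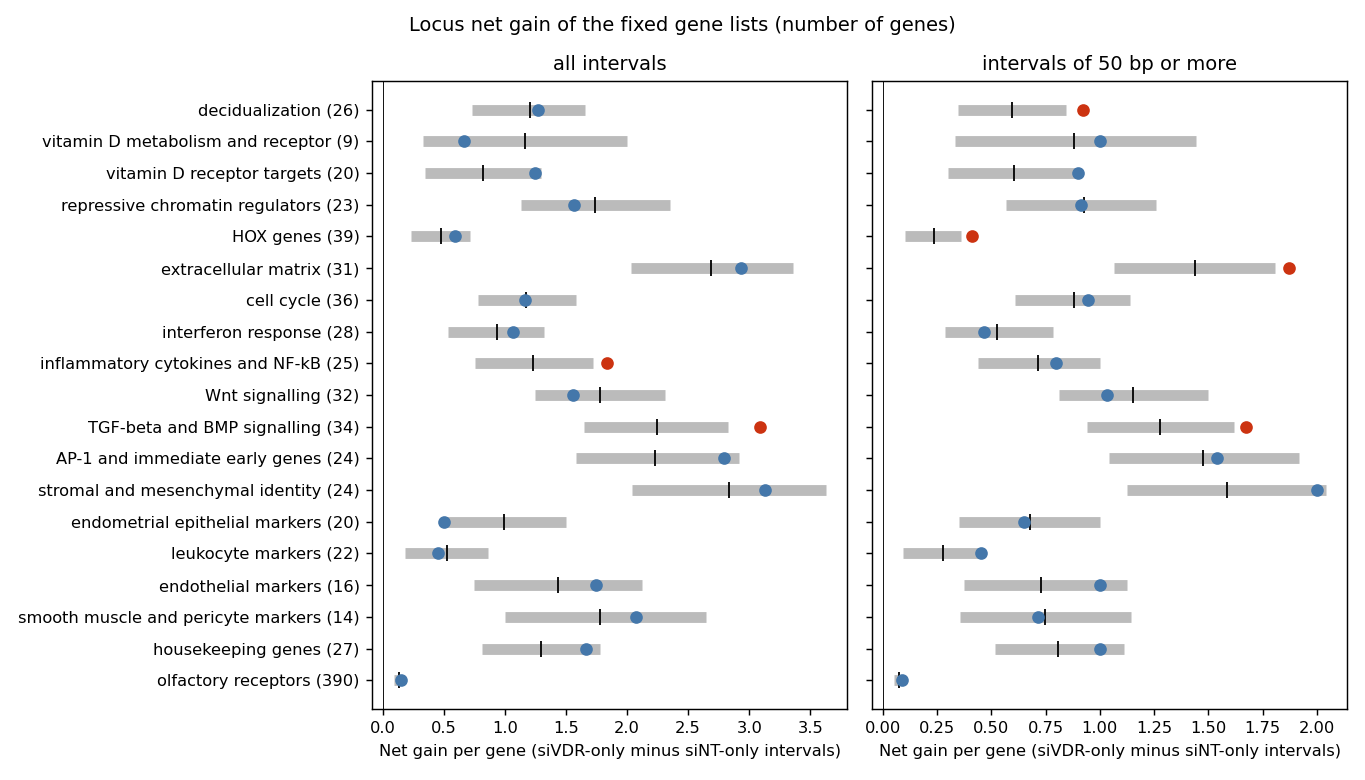
Net gain per gene (horizontal axis, siVDR-only minus siNT-only intervals nearest to the gene) for the 19 fixed gene lists, with the number of genes in parentheses, for all intervals and for those of 50 bp or more. Grey bars are the central 95% and black ticks the mean of 10000 matched random lists, and red points lie above the bar. TGF-beta and BMP signalling lies above its bar in both panels, at 3.09 and 1.68.

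The genes with the largest net gain of nearest sites were GLI2, a transcription factor of Hedgehog signalling, with 16 siVDR-only and 2 siNT-only sites, H4C8, a histone H4 gene, with 13 and 0, and MITF, a transcription factor, with 16 and 3. HS1BP3, KLF13, TRAM2, MCFD2, SUSD1 and LRRC8D had a net gain of 12 sites, and CTC1 of 11. Net losses were smaller. The salivary protein gene PRB4 had 5 siNT-only and no siVDR-only sites, DEPDC5, OR2AP1 and HSPG2 had a net value of -4, and DENND4A, SMARCA5, TTC34, PIGG, PRR5 and GRHL2 of -3. The widest siVDR-only interval, 542 bp at chromosome 4, 54281176 to 54281717, lay in the PDGFRA gene, 16.8 kb from its nearer end. The next were 539 bp in MB21D2 (chromosome 3, 192833230 to 192833768), 427 bp between genes at chromosome 1, 218706130 to 218706556, 425 bp in ME3 (chromosome 11, 86578099 to 86578523) and 421 bp between genes at chromosome 9, 84122087 to 84122507. The 5 widest siNT-only intervals were 184 to 251 bp. The widest lay in TENM4 (chromosome 11, 79182861 to 79183111) and the next, of 238 bp, in APP (chromosome 21, 26153877 to 26154114). The others lay between genes near SPTLC2 and MAP2K3 and in PHYHIP.

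**Figure D3:**
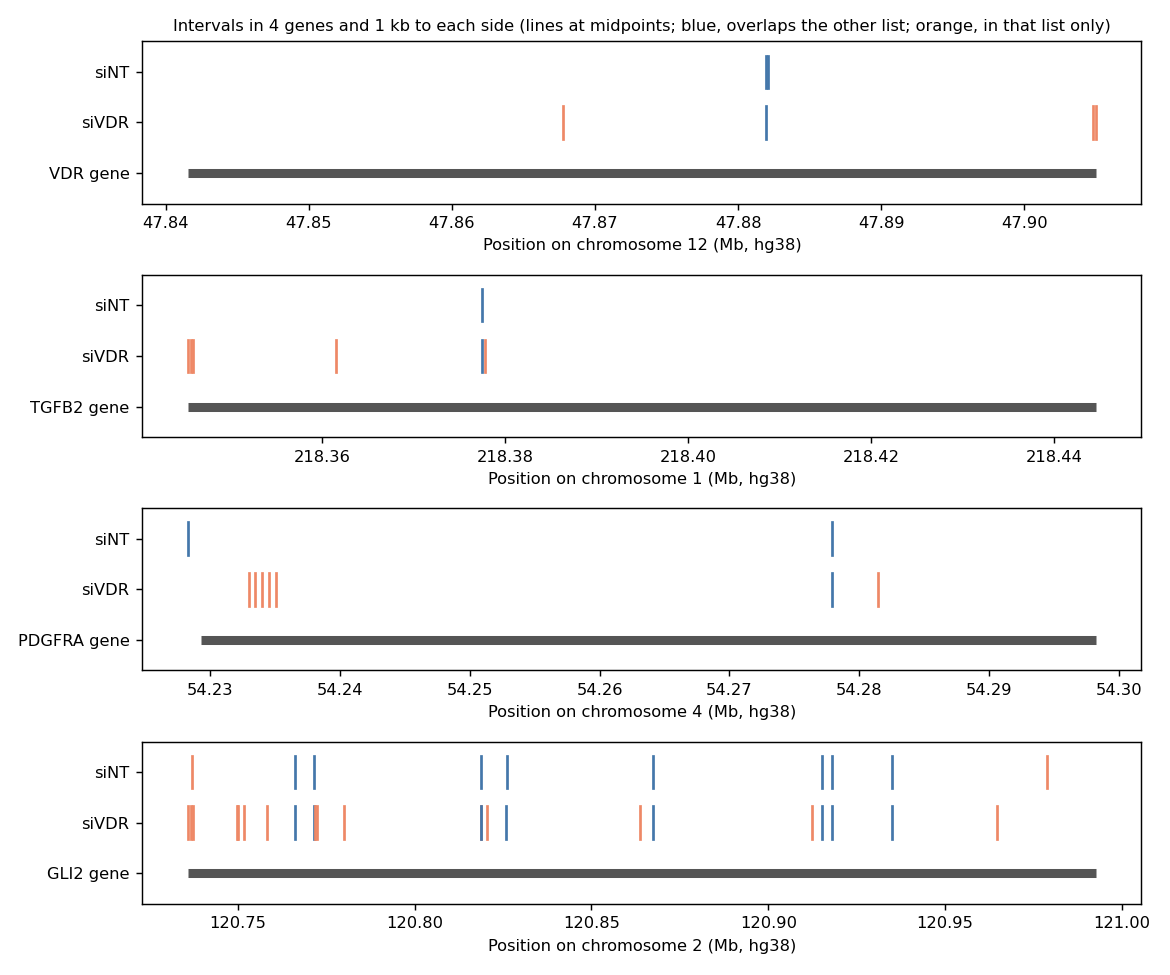
Intervals of the siNT and siVDR lists in 4 genes and 1 kb to each side (horizontal axis, position in Mb on hg38), drawn as lines at their midpoints. Blue intervals overlap the other list and orange ones are in that list only, and dark bars are the genes. VDR had 3 siVDR-only intervals, and PDGFRA held the 542-bp siVDR-only interval at its right.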

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

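The limit of 50 bp in both lists, the matching on intervals in both lists, the assignment to gene spans, the leaving out of member genes and the comparison within width classes were chosen after seeing the data. No paired analysis was possible because each group was given as 1 list, and leaving out a library was not possible for the same reason. Motif content and the ends of single transcripts were not run, since no genome sequence or transcript table was used, and the lists hold no scores, so width took their place. The libraries were sampled to a common depth per the design text, but its value is unknown, and how far it limits the lists cannot be stated.

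The siVDR list was the longer in all settings that leave the lists at their own lengths. The ratio of interval numbers was 2.28 at 200 bp or more and 1.97 at 50 bp or more, against 1.62. The share of siNT intervals also in siVDR (79.7%) became 93.8% at 200 bp or more, 92.9% at 50 bp or more, 38.1% with reciprocal overlap of 50%, 87.9% by midpoints, 70.4% with lists of equal length and 88.3% in the widest 50% of each list. The share of siVDR intervals also in siNT (46.3%) became 41.1%, 23.5% with reciprocal overlap, 54.7% by midpoints, 65.5% with equal length and 52.8% in the widest 50%, the first at 200 bp or more. It stayed below the siNT share in each of these settings, but was above 50% in the last 3, and the siNT share was below 50% with reciprocal overlap.

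The shares near gene ends kept their order, shared intervals above both others. For shared, siVDR-only and siNT-only intervals they were 39.0%, 24.2% and 26.8% with reciprocal overlap, 36.0%, 22.6% and 20.5% with equal length, 30.0%, 16.2% and 14.3% within 500 bp, 38.6%, 27.2% and 24.4% within 2.5 kb, 41.2%, 28.6% and 25.04% with all annotated genes, and 40.1%, 23.7% and 22% at 50 bp or more. With reciprocal overlap the siNT-only share was above the siVDR-only share, in contrast to the other settings. Genes with a gene end in siVDR only numbered 1026 and in siNT only 597 with lists of equal length, against 1825 and 188. That setting removes narrow siVDR intervals by construction. For the other shifts the cause was not tested.

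Of the 19 gene lists, 3 lay beyond the central 95% for gene ends, and 1, smooth muscle markers, with lists of equal length and 5 when matched on intervals in both lists. For nearest sites 2 did, against 1 with equal length, vitamin D receptor targets, which was not among the 2, and against 7 with unmatched random lists, 7 when matched on intervals in both lists and 4 at 50 bp or more, namely decidualization, HOX, extracellular matrix and TGF-beta genes. At 50 bp or more, the gene-end percentile of vitamin D receptor targets went from 99.01 to 46.6 and that of smooth muscle markers from 1.74 to 63.9, each to the other side of the middle. Matching on intervals in either list takes up part of the net itself, by construction. Of 232 list percentiles under alternatives, 198 kept their side of the limits, 22 moved out of the central 95% and 12 moved into it. Direction was less stable, and 55 of the 232 crossed the 50th percentile, 51 of them inside the central 95% in both settings.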

Other observations

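Among the tests in this part, those on wide siNT intervals, on the ratio per chromosome, on the median distance to shared intervals, on the ratio on chromosomes without receptor targets and on 9-bp intervals near gene ends were chosen only after the result was seen, as were all values limited to intervals of 50 bp or more and the genes named from them. Wide intervals gave another picture of decidualization and HOX genes than all intervals did. With both lists limited to 50 bp or more, 8 of 26 decidualization genes had a gene end in siVDR only and none in siNT only: FOXO1, HAND2, HOXA10, HOXA11, IL15, FKBP5, DCN and BMP2. The list had 25 siVDR-only and 1 siNT-only nearest sites, at the 99.5th percentile of matched random lists, and lay at the 98.9th for gene ends. HOX genes also had 8 gene ends in siVDR only and none in siNT only, HOXA9, HOXA10, HOXA11, HOXB13, HOXD1, HOXD9, HOXD10 and HOXD11, at the 99.3rd percentile for gene ends and the 99.4th for nearest sites. The lists share 2 genes. In each of them, 7 of the 8 genes had a narrower siNT interval near a gene end, which need not overlap the siVDR interval. Over all genes the same was true of 1906 of 2566, or 74.3%. Leaving out HAND2 put decidualization at 97.3 for gene ends, inside the central 95%. The lowest value without 1 gene was 98.3 for its nearest sites, and 97.8 and 98.6 for HOX genes. Neighbouring HOX genes can share an interval, which neither the random lists nor leaving out 1 gene takes into account. HOXB13 and HOXD11 had no siVDR-only interval of this width among their nearest sites. Extracellular matrix genes lay at 98.6 for nearest sites and at 97.2 without LAMA4.

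Genes outside the protein-coding set differed in how often they had an interval near an end. Of 429 tRNA genes, 48.2% had one in both lists and 15.6% in siVDR only, against 17.5% and 6.41% of 18177 lncRNA genes, 8.53% and 4.45% of 1911 miRNA genes, and 2.13% and 1.81% of 15212 pseudogenes. In siNT only, the shares were 0.466%, 0.814%, 0.419% and 0.309%. Symbol families were compared with 2000 random lists each, which was not planned. Among 97 symbol families of at least 20 genes, 8 lay beyond the central 95% for gene ends and 12 for nearest sites. By chance, 4.85 of each were to be expected if genes varied independently. The families named next were picked from those beyond the limits, and random lists do not copy neighbouring genes. C-type lectin genes (CLEC) had 3 of 31 gene ends in siNT only and none in siVDR only. Mediator subunit genes (MED) had 7 of 30 in siVDR only and none in siNT only, at the 98.3rd percentile. For nearest sites, CLEC lay at the 0.6th percentile and MED at the 11.75th, the latter inside the central 95% and below the middle. Cytochrome P450 genes (CYP) lay at the 0.0500th percentile for nearest sites and at the 3.45th for gene ends. Both lists held intervals over mitochondrial-like pseudogenes on chromosome 1, 548 bp in siNT and 591 bp in siVDR at MTND2P28, and 625 bp in both at MTATP6P1.

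For the longer siVDR list, a difference limited to some chromosomes is argued against by the lowest ratio of any chromosome, 1.497, and flanks of shared sites as the source of most siVDR-only intervals by their median distance of 10.9 kb to the nearest shared interval. For the 27.7% within 1 kb of a shared interval, flanks and separate sites cannot be told apart. For opening limited to the 20 listed receptor targets, the ratio on the 11 chromosomes that hold none of them was 1.62 (1.59 to 1.65). This could hardly have come out otherwise, since no 20 genes held more than 0.628% of siVDR-only intervals, and the listed targets held 0.0712%. It shows only that these 20 genes do not make up the excess. Opening limited to other sites bound by the receptor was not tested. Open is a higher yield or sensitivity in the siVDR pool over all sites, since 99.9% of siNT intervals of 200 bp or more were also in siVDR and paired sites were wider there. Per the design text the libraries were sampled to a common depth, but that does not equalize the signal at open sites. General opening of chromatin after knockdown could give the same values, and without levels or single libraries it was not tested.

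The 9-bp intervals, as wide as 1 trimmed read, were tested as cuts stacked by chance over the genome. Their share near gene ends was 8.74 times that of randomly placed intervals, which argues against that as the whole source. The share was 7.50 times for those in siNT only and 8.29 times for those in siVDR only. Low signal at open sites, near the limit of calling, is a candidate explanation that was not tested. No biological explanation was tested.

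For the 3 lists that lay above matched random lists, narrow intervals, 1 member gene and the length of the siVDR list were weighed. The TGF-beta and BMP list stayed at 98.8 with intervals of 50 bp or more and at 98.9 without TGFB2, which argues against each alone, but it was 95.7 with both limits, without SMAD3. It was 93.9 with lists of equal length, a setting that drops only the narrowest siVDR intervals and keeps all siNT ones. The number of siVDR intervals may account for its position, but this setting cannot separate number from width, for any of the 3 lists. For the inflammatory list, all 3 stay open, at 72.1 by width, 94.6 without NFKBIA and 75.8 with equal length. The receptor targets likewise gave 46.6, 96.9 without CD14 and 69.4 for gene ends, while their nearest sites, at 96.7, ranged from 72.2 with unmatched random lists to 98.0 with equal length, and a response to loss of the receptor stays open, untested, for all 3 lists.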
